A study of Mus musculus with 32 samples.

How the data were processed

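RNA of 32 single mouse oocytes was measured, 1 library per oocyte. Libraries were made with a SMART-Seq v4 kit for low input, per the labels. As background, this kit primes cDNA synthesis on poly(A) tails, so a value can reflect both the amount of a transcript and its tail. The labels place the oocytes in 4 groups by stage and by treatment of the follicle. There were 4 germinal vesicle (GV) oocytes from fresh and 4 from vitrified follicles, taken on day 8 of culture, and 12 metaphase II (MII) oocytes from each treatment, taken on day 9. Each oocyte is called a biological replicate in the labels, and the mouse or culture it came from is not given in the sources used here.

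HISAT2, featureCounts and the mouse genome build mm10 are named in the submitters' processing notes, without versions or settings. The unit of the deposited values is not named in the labels, and was read from the values: those of GV oocytes are whole, as counts are, and those of MII oocytes resemble expected or estimated counts, since 11.4% to 19.4% of them per oocyte are not whole. The authors' step that made them fractional is not given in the sources used here. The tests had been planned for counts, so all values were rounded to whole numbers and taken as counts. The table has 13202 entries, of which 27 exact repeats were removed, leaving 13175 genes. Each gene had a total of at least 10 over the MII oocytes, and 376 genes were at 0 in all GV oocytes, so the table was limited on MII values. It holds 0 mitochondrially encoded genes, so their share of counts could not be computed and the list made for them was not tested. Gene symbols were matched to GENCODE M21 on GRCm38 (13059 of 13175) for positions and sequences and to RefSeq (13168 of 13175) for names.

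Depth per oocyte ran from 5300208 to 17687247 counts. Library sizes were scaled with the trimmed mean of M values (TMM), and CPM values (counts scaled to 1e6 in total) use the scaled sizes. Genes with low counts were left out with filterByExpr of edgeR 4.0.16 at its minimum of 10 counts and 15 in total. Vitrified and fresh oocytes were compared within each stage, and the stages within each treatment and the interaction of stage with treatment were taken from 1 fit of all 32 oocytes with 4 group means. Every comparison used the quasi-likelihood F test of edgeR in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05. Errors of log2 fold changes are standard errors from that test, and errors of CPM are standard deviations. The 95% interval of each log2 fold change was also computed, and the share of genes whose interval lay between −1 and 1 is given because the absence of a call does not show that values were equal.

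Gene lists, 22 in number, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, where at least 5 members were tested, with adjustment over the lists of a comparison. Adjusted p with an estimated correlation is given beside each list that passed. Counts adjusted over the list alone are given beside those over all genes. The share of expression variance between groups was computed on log2 CPM with a prior count of 2 and tested over all 35 splits of the 8 GV oocytes or with 100000 relabelings of the MII oocytes, one-sided. The distance of an oocyte is 1 minus Spearman's rho to the mean profile of the other oocytes of its group, and groups were compared by two-sided exact permutation tests (GV) or permutation tests with 100000 resamples (MII). Library quality values were compared in the same way.

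The groups, comparisons, gene lists, rule for named genes and alternatives to be run were fixed before the data were examined. The rule names, per comparison, the 12 largest rises and 12 largest falls among genes past the threshold with a mean log2 CPM of at least 4 and an established symbol. Where fewer than 5 passed in a direction, the genes with the smallest p were added to make 5. It also names up to 4 members of each list with the smallest p, and 16 genes fixed by name, some of which are left out of the text for brevity. Library numbers in the labels run from 2 to 13 and from 20 to 25 among MII oocytes, in both treatments (7 and 5 oocytes per treatment), and these were taken as a possible batch. GV libraries carry numbers from 81 to 85, so no batch holds both stages.

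The edgeR steps were tested on simulated counts drawn with the means, spread and library sizes of the real oocytes, with 100 genes changed 2-fold and 100 changed 4-fold. In the GV comparison 1% of the 2-fold and 21% of the 4-fold changes were recovered, over 10831 genes. In the MII comparison 44% and 86% were recovered over 8428 genes, with 6 false calls. In the stage comparison of fresh oocytes 8% and 53% were recovered over 11470 genes, with 2 false calls. A list of genes shifted by 0.5 on the log2 scale was called in 10 of 10 simulations of each comparison. Genes were simulated independently of one another, so this cannot show how the list test behaves where members vary together. In the real MII comparison the estimated correlation was 0.66 for ribosomal proteins and 0.53 for oxidative phosphorylation.

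Alternatives were size factors by relative log expression (RLE), no filter or a stricter filter (CPM of at least 10), DESeq2 1.42.0, limma-voom with quality weights, 1 fit of all 32 oocytes, a replicate block, the library-number series as a covariate or each series alone, other distance measures, counts thinned to the smallest total, and leaving out each oocyte. Fits without 4 MII oocytes with high values of genes known from cumulus cells, and fits of only the genes with whole values in all MII oocytes, were added after the data were seen. Other splits of the oocytes into groups of the same sizes were refitted, all 35 for GV and 100 for each other comparison.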

Results

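Vitrification cools a follicle into a glass-like state for storage. To ask whether it alters the transcripts of the oocyte that later grows and matures in that follicle, preantral mouse follicles were vitrified or kept fresh, grown in encapsulated in vitro culture and taken to ovulation, and 32 single oocytes were sequenced. GV oocytes are fully grown and arrested before the meiotic divisions, while MII oocytes are ovulated eggs ready for fertilization. Total counts ran from 10357543 to 17687247 in 4 fresh GV oocytes, from 11159677 to 16554201 in 4 vitrified GV oocytes, from 6196976 to 10142902 in 12 fresh MII oocytes and from 5300208 to 12206512 in 12 vitrified MII oocytes. In GV oocytes 11654 ± 278 (SD, n = 4) genes were detected after fresh culture and 11336 ± 430 (SD, n = 4) after vitrification. The corresponding numbers in MII oocytes were 10652 ± 521 and 10332 ± 629 (SD, n = 12 each). The p-values of single genes and of permutation tests below rest on the spread between oocytes, which may share a mouse or a culture. Those of gene lists set the members against the other genes and take genes as nearly independent.

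**Figure D1:**
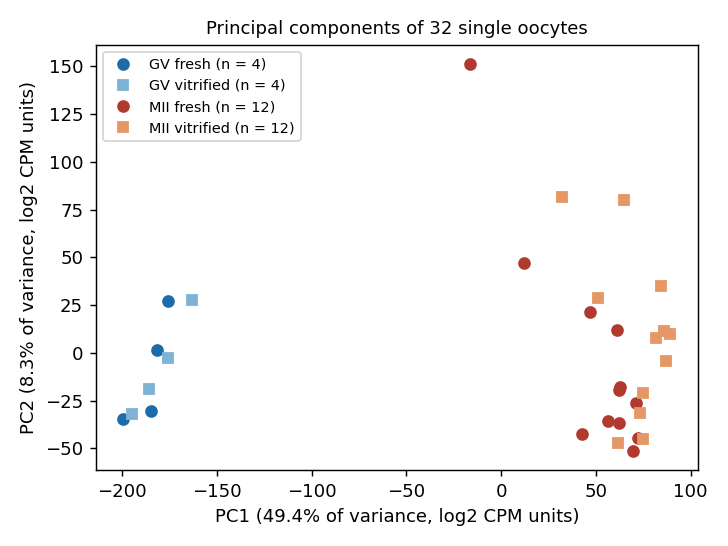
Principal components of log2 CPM in 32 single oocytes, 1 point per oocyte, coloured by group, with PC1 holding 49.4% and PC2 8.30% of the variance. All 8 GV oocytes lie below −163 on PC1, and MII fresh replicate 11, at −16.2, is the MII oocyte nearest to them.

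Did vitrification of the follicle change the GV oocyte? Transcripts of cytosolic ribosomal proteins fell as a group in vitrified GV oocytes, with 73 of 85 members below 0 and a median log2 fold change of −0.41 (adjusted p = 1.63e-13). Nuclear subunits of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, fell by 0.34 in the median of 60 members (adjusted p = 2.65e-06). Replication-dependent histones, which package newly made DNA, fell by 0.65 in the median of 23 members (adjusted p = 8.07e-04). Most of these were low: with the stricter filter (CPM of at least 10) 6 were left, with a median of −0.77 (adjusted p = 0.0305). With an estimated correlation, the adjusted p of each of these 3 lists was 0.573. With fry it was 0.402, 0.517 and 0.447, in the order given. As a mean per oocyte, the ribosomal protein score differed by −0.40 (exact permutation p = 0.0857) and the oxidative phosphorylation score by −0.28 (exact permutation p = 0.143), each with an adjusted p of 0.286 over 10 such tests. The small ribosomal subunit gene Rps29 had 741 ± 139 CPM in fresh and 440 ± 25.1 CPM in vitrified GV oocytes (SD, n = 4 each), a log2 fold change of −0.75 ± 0.26 (SE, unadjusted p = 0.0127 by edgeR). The complex I subunit Ndufs5 had 338.5 ± 83.4 and 199 ± 27.6 CPM (log2 fold change −0.76 ± 0.27, SE).

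No single gene passed in GV oocytes: edgeR called 0 of 10831 genes, with 180 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0 (251 and 645 unadjusted). The smallest unadjusted p belonged to Kbtbd11, a gene of chromosome 8 (15011025 to 15033333, GRCm38), at a log2 fold change of −1.59 ± 0.41 (SE). Cox6b2, a testis-type subunit of cytochrome c oxidase on chromosome 7 (4751792 to 4753094), measured 227 ± 38.1 CPM in fresh and 111 ± 20.1 CPM in vitrified oocytes (SD, n = 4 each). Among genes measured higher, Rfc4, which loads the replication clamp onto DNA, had a log2 fold change of 1.52 ± 0.42 (SE) and the nuclear pore gene Ranbp2 one of 1.69 ± 0.50 (SE). The neighbouring X-linked genes Xlr3b and Xlr3c, near-identical copies whose reads cannot be assigned with certainty, had 2.30 ± 0.73 and 2.83 ± 0.88 (SE). For all of these genes the adjusted p was 1.

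Lists of oocyte identity and stress did not pass in GV oocytes. Genes of oocyte identity and the zona pellucida, the egg coat, had a median of −0.15 over 18 members (adjusted p = 0.416). Maternal effect factors, which the embryo inherits, had a median of −0.18 over 26 members, a mean of 0.04 and an adjusted p of 0.767. Heat and cold shock genes had a median of 0.15 over 24 members (adjusted p = 0.223), endoplasmic reticulum stress genes 0.17 over 27 (0.223), antioxidant enzymes −0.09 over 32 (0.317) and genes of apoptosis and the DNA damage response −0.09 over 29 (0.836, with the test pointing up). Endoplasmic reticulum stress genes passed without fresh replicate 4 (median 0.37, adjusted p = 0.00472), and spindle genes, at 0.23 over 29 members (0.223), passed without vitrified replicate 3 (0.27, adjusted p = 0.0456). Adjusted over the list alone, 0 members of any list passed. Of single genes, the growth factor Gdf9 had 3203 ± 1226 and 2435 ± 930 CPM, and the cell cycle gene Ccnb1 835 ± 460 and 1209 ± 875 CPM, in fresh and vitrified oocytes (SD, n = 4 each).

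Treatment took 11.5% of the expression variance of GV oocytes (exact p = 0.8286 over 35 splits), and the median over all splits was 12.7%. Oocytes stood at a distance of 0.0703 ± 0.0276 from their group after fresh culture and 0.0781 ± 0.0406 after vitrification (SD, n = 4 each), with a difference of 0.00785 (exact permutation p = 0.771). The 95% interval of the log2 fold change lay between −1 and 1 for 18.9% of genes, so a 2-fold change was outside the interval for that share alone, and for 10.0% to 12.1% when any 1 of fresh replicates 1 and 2 and vitrified replicates 2, 3 and 4 was left out. Without fresh replicate 3, the adjusted p was 0.0704 for the oxidative phosphorylation list (median −0.16) and 0.110 for the histones (median −0.41).

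Did vitrification change the MII oocyte? The lists of the ribosome and of mitochondrial respiration passed, as in GV oocytes, while the histones did not (median 8.3e-04 over 6 members, adjusted p = 0.840). All 53 tested ribosomal protein genes were lower in vitrified MII oocytes, with a median of −0.97 (adjusted p = 9.49e-08), and oxidative phosphorylation subunits had a median of −0.93 with 45 of 49 below 0 (adjusted p = 9.89e-09). With an estimated correlation the adjusted p of both lists was 0.914, and with fry it was 0.734. Cox6c, a subunit of cytochrome c oxidase on chromosome 15 (35925886 to 35938246), had the smallest p of all genes, with 72.0 ± 34.4 CPM in fresh and 28.9 ± 7.98 CPM in vitrified MII oocytes (SD, n = 12 each) and a log2 fold change of −1.31 ± 0.25 (SE, adjusted p = 0.125 by edgeR). Rplp1, a protein of the ribosomal stalk, measured 12.5 ± 9.15 and 4.06 ± 1.93 CPM (SD, n = 12 each). Adjusted over the list alone, 19 oxidative phosphorylation subunits fell, among them Cox6a1 (log2 fold change −1.66) and Cox7a2 (−1.04), and Ndufa10 rose, while Rplp1 was the 1 ribosomal protein that fell.

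edgeR called 0 of 8428 genes in MII oocytes, with 1052 at an unadjusted p under 0.05 (499 higher, 553 lower). limma-voom called 0 (1334 unadjusted), while DESeq2 called 52 genes, 20 higher and 32 lower (1057 unadjusted), so the count depends on the tool. Cox6c passed in DESeq2 (adjusted p = 0.00110), in edgeR with a stricter filter (adjusted p = 0.0430), in the fit of all 32 oocytes (adjusted p = 0.0209) and when fresh replicate 6 or 8 was left out. After Cox6c, the lowest p among genes measured lower were those of Pebp1, an inhibitor of Raf kinase signalling (log2 fold change −1.43 ± 0.33, SE), the chaperonin subunit Cct2 (−0.77 ± 0.19), the translation initiation factor Eif3k (−1.10 ± 0.27) and Vkorc1, which recycles vitamin K (−1.19 ± 0.30). Among genes measured higher were the palmitoyltransferase Zdhhc13 (0.60 ± 0.13), the vesicle traffic gene Sytl4 (0.52 ± 0.12), the mitochondrial lipid kinase Agk (0.63 ± 0.15) and the DNA polymerase subunit Pole3 (0.53 ± 0.13). These 8 genes had an adjusted p of 0.186 in edgeR and were among the DESeq2 calls, at an adjusted p of 0.00973 (Zdhhc13, Sytl4) to 0.0315 (Pole3).

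Other lists did not pass in MII oocytes. Maternal effect factors had a median of −0.19 over 25 members (adjusted p = 0.370), and adjusted over the list alone Khdc3, part of the subcortical maternal complex, fell (log2 fold change −1.17). This list passed without fresh replicate 11 (−0.22, adjusted p = 0.0219) and within library numbers under 20 (−0.34, adjusted p = 0.0323). In the list of maternal mRNA storage and decay (median −0.05 over 42 members, adjusted p = 0.569), the helicase Ddx6 (−1.09) and the poly(A) polymerase Papolg (39.2 ± 17.97 CPM in fresh and 19.7 ± 7.69 CPM in vitrified oocytes, SD, n = 12 each) fell by the same measure. In the meiotic list (median 0.08, mean −0.05 over 33 members, adjusted p = 0.693), Ensa (−0.90) and Mapk3 (−0.85) did. Antioxidant enzymes had a median of −0.02 over 25 members and a test pointing up (adjusted p = 0.873), and there the secreted peroxidase Gpx3 rose (0.59) adjusted over the list alone. Heat and cold shock genes (median 0.05, mean −0.08, over 22 members), endoplasmic reticulum stress genes (median 0.01, mean −0.08, over 24) and apoptosis genes (median 0.02, mean −0.03, over 26) had adjusted p of 0.840, 0.693 and 0.693. The egg coat gene Zp3 measured 442 ± 198 and 298 ± 72.2 CPM, Gdf9 5457 ± 1341 and 6803 ± 1012 CPM, and Ccnb1 7404 ± 1529 and 9437 ± 2730 CPM, in fresh and vitrified oocytes (SD, n = 12 each), none of them past the test over all genes.

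In some MII oocytes, genes known from cumulus cells, the somatic cells around the egg, were high. Genes of cumulus expansion and ovulation summed to 1010 CPM in MII fresh replicate 11, 235 in vitrified replicate 12, 99.0 in fresh replicate 1 and 92.0 in vitrified replicate 1, each more than 3 times the MII median. Ribosomal protein transcripts moved with this signal, summing to 5456 CPM in fresh replicate 11 against 1528 ± 1340 in all fresh MII oocytes (SD, n = 12) and 977 ± 362 in vitrified MII oocytes (SD, n = 12, permutation p = 0.160). Without fresh replicate 11 alone, the list medians were −0.39 for ribosomal proteins (adjusted p = 0.0141) and −0.40 for oxidative phosphorylation (4.47e-04). Without all 4 oocytes they were −0.43 (adjusted p = 0.00168) and −0.42 (1.28e-04), an alternative chosen after the data were seen, and edgeR then called 0 genes (907 unadjusted).

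Within library numbers under 20 the medians were −0.45 for ribosomal proteins (adjusted p = 0.0197) and −0.46 for oxidative phosphorylation (0.0114), and within numbers of 20 and over −1.37 and −1.06. Proteasome subunits (median −0.26 over 32 members, adjusted p = 0.410) and actin genes (−0.25 over 30, adjusted p = 0.569) passed only within numbers of 20 and over (−0.62 and −0.23), and maternal mRNA storage and decay only within numbers under 20 (−0.25). As a mean per oocyte, the ribosomal protein score differed by −0.51 (permutation p = 0.191) and the oxidative phosphorylation score by −0.51 (p = 0.0777), with adjusted p of 0.319 and 0.286 over 10 such tests. The list test treats genes as nearly independent, and it gave the ribosomal proteins an unadjusted p under 0.05 in 94 of 99 other splits of the MII oocytes and in 20 of 34 other splits of the GV oocytes. For oxidative phosphorylation these numbers were 82 and 21, and for histones in GV oocytes 12 of 34.

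**Figure D2:**
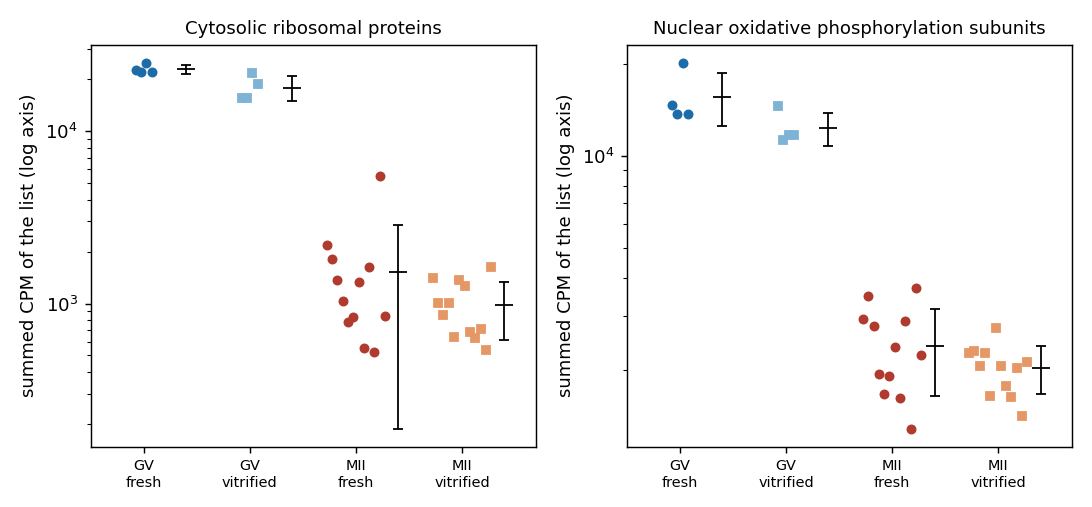
Summed CPM, on a log axis, of cytosolic ribosomal protein genes (left) and nuclear oxidative phosphorylation genes (right) in each oocyte, with the mean and SD of each group in black. GV oocytes hold 15452 CPM or more of ribosomal protein transcripts, and the highest MII oocyte, fresh replicate 11, holds 5456.

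Treatment took 6.10% of the variance among MII oocytes (permutation p = 0.0942, with 4.06% in the median relabeling, and p = 0.0681 when labels moved within the library series). The p was 0.0445 without vitrified replicate 9, at 7.14%. Fresh MII oocytes stood at a distance of 0.0615 ± 0.0325 from their group and vitrified ones at 0.0519 ± 0.0141 (SD, n = 12 each), a difference of −0.00960 (permutation p = 0.453) that was 0.00299 within numbers under 20, −0.0308 within numbers of 20 and over and −2.41e-04 without fresh replicate 11. The 95% interval lay between −1 and 1 for 63.7% of MII genes.

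Which transcripts differed between GV and MII oocytes after fresh culture? In all, 2610 genes were higher and 3405 lower in MII oocytes, of 11470 tested by edgeR, and stage took 50.8% of the variance of fresh oocytes (exact permutation p = 5.49e-04, the smallest 1820 relabelings can give). Genes of meiotic maturation rose, with a median of 1.33 over 35 members, 20 higher and 8 lower (adjusted p = 7.35e-04, and adjusted p = 0.329 with an estimated correlation). Among its 10 members with whole values in all MII oocytes the median was −0.16 (adjusted p = 0.150). Ccnb1, the cyclin that drives entry into M phase (chromosome 13, 100778650 to 100786570), rose from 835 ± 460 CPM (SD, n = 4) to 7404 ± 1529 CPM (SD, n = 12), a log2 fold change of 3.13 ± 0.36 (SE, adjusted p = 4.07e-09), with values that were not whole in 21 of 24 MII oocytes. The cyclin Ccna2 (2.51 ± 0.24), the Mos target kinase Map2k1 (2.71 ± 0.21), the oocyte kinase Wee2 that holds CDK1 in check (2.14 ± 0.18) and the phosphodiesterase Pde3a that lowers cAMP (2.88 ± 0.29) rose with it. Mos, the kinase that starts this cascade, rose by 1.17 ± 0.48 (adjusted p = 0.0392), a call lost when any 1 of GV fresh replicates 1, 2 and 3 or MII fresh replicates 2, 3, 5 and 6 was left out, and with MII library numbers of 20 and over only (0.25, adjusted p = 0.670).

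Genes of the spindle, kinetochore and cohesion rose in the median by 1.04 over 29 members, 14 higher and 4 lower (adjusted p = 0.00517, and 0.378 with an estimated correlation), and the 8 members with whole MII values had a median of 2.16. Sgo2a, which protects centromeric cohesin, rose by 2.36 ± 0.22 (SE) and the microtubule polymerase Ckap5 by 1.60 ± 0.20, whereas the spindle factor Tacc3 fell by 2.35 and Birc5, a subunit of the chromosomal passenger complex, fell by 2.29. In the list of maternal mRNA storage and decay, 18 members rose and 6 fell, with a median of 0.55 over 45 members (adjusted p = 0.101). Btg4, the adaptor that brings the deadenylase to maternal mRNA (chromosome 9, 51060901 to 51119875), rose from 3063 ± 1769 CPM (SD, n = 4) to 11540 ± 2469 CPM (SD, n = 12), and the deadenylase Cnot7 rose by 3.12 ± 0.42 (SE, adjusted p = 8.75e-08), not whole in 18 and 20 of 24 MII oocytes. Actin and cortex genes had 16 higher and 6 lower members and a median of 0.60 over 33 (adjusted p = 0.0938), including the actin nucleator Spire1 (2.29 ± 0.28).

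**Figure D3:**
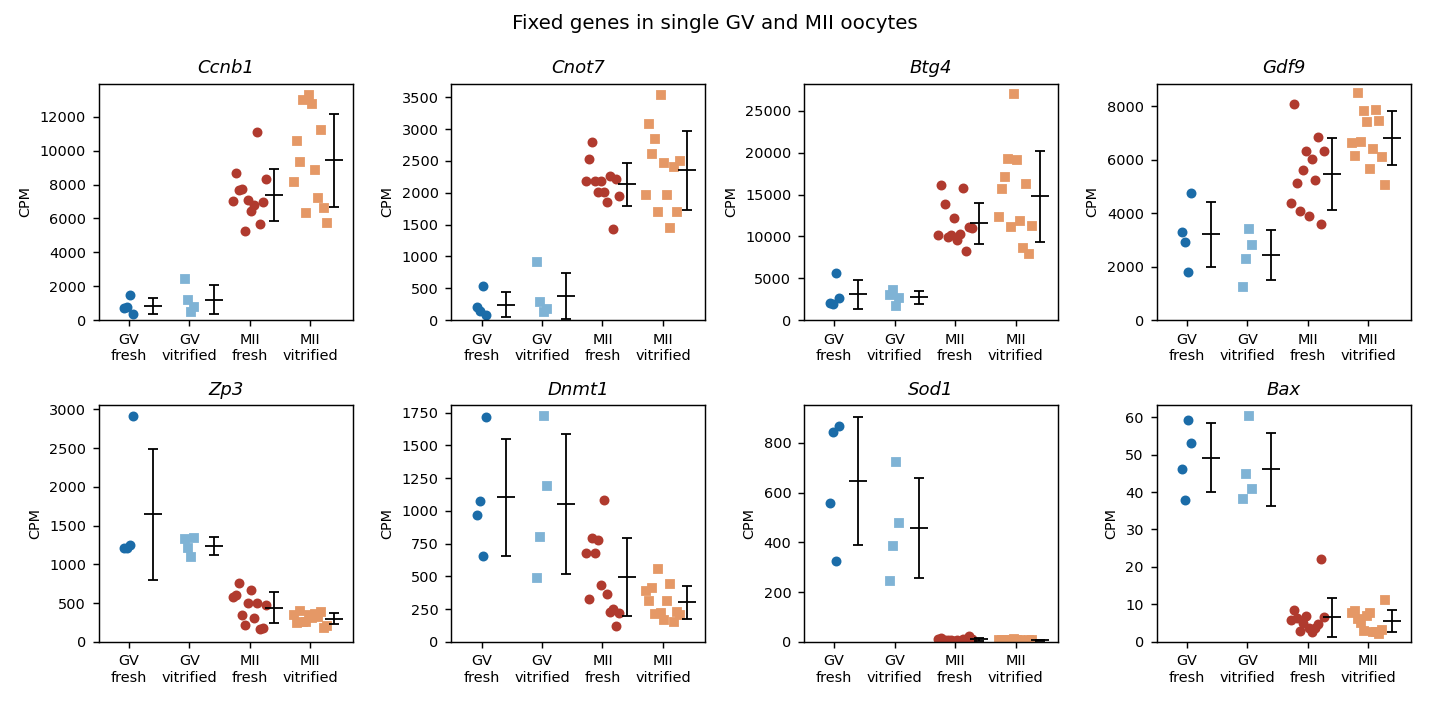
CPM of 8 fixed genes in each oocyte, by group, with the group mean and SD in black. Ccnb1, Cnot7, Btg4 and Gdf9 are higher in MII than in GV oocytes of both treatments, and Zp3, Dnmt1, Sod1 and Bax are lower, each past the edgeR test in both stage comparisons.

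Housekeeping complexes fell. All 85 ribosomal protein genes were lower in fresh MII oocytes, 77 past the test, with a median of −4.57 (adjusted p = 9.33e-22), and in oxidative phosphorylation 51 of 62 fell and 6 rose, with a median of −3.65 (adjusted p = 1.08e-13). Proteasome subunits had a median of −1.96 over 36 members, 23 lower and 4 higher (adjusted p = 7.35e-04), and replication-dependent histones −3.12 over 23 members, 16 lower and 0 higher (adjusted p = 0.00687). With an estimated correlation the adjusted p of these lists was 0.367, 0.367, 0.410 and 0.367. With fry it was 5.5e-11, 2.0e-10, 1.7e-08 and 5.5e-11, and 1.65e-09 and 1.83e-06 for the meiotic and spindle lists. In this comparison fry also passed lists that did not pass with camera, among them oocyte identity genes (adjusted p = 0.0155). With the stricter filter 6 histones were left (median −4.09, adjusted p = 0.00895). Random genes matched on length, GC content and expression fell too, with medians of −2.55 for ribosomal proteins and −1.88 for oxidative phosphorylation. Part of both falls was thus shared by genes of like length, GC content and expression. Rps29 went from 741 ± 139 CPM (SD, n = 4) to 3.86 ± 3.71 CPM (SD, n = 12), a log2 fold change of −7.60 ± 0.52 (SE). The respiratory subunits Ndufb11 (−5.88 ± 0.28) and Uqcrq (−6.79 ± 0.81), the proteasome subunit Psma7 (−2.13 ± 0.17) and the histone H2bc1 (−6.68 ± 0.74) fell too. Sod1, the cytosolic superoxide dismutase (chromosome 16, 90220754 to 90226329), fell by 6.13, the cell death gene Bax fell by 2.92 and the cytochrome c gene Cycs fell by 3.54.

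Among the largest falls outside these complexes were 5 genes that share no 50-base word with other genes and have whole values in every MII oocyte. Setd4, a methyltransferase gene on chromosome 16 (93583457 to 93604063), went from 2325 ± 281 CPM (SD, n = 4) to 34.2 ± 17.4 CPM (SD, n = 12), although 1.12% of its exons overlap another gene. Cpsf4l, a relative of a polyadenylation factor (log2 fold change −7.00 ± 0.31), Zar1l, a relative of the maternal factor Zar1 (−6.57 ± 0.31), Gtsf1, a germ cell factor of transposon silencing (−6.20 ± 0.35), and the glutathione transferase Gsta4 (−5.98 ± 0.33) fell as far. Oocyte identity genes split into 7 higher and 7 lower (median 0.07, mean −0.48, over 18 members, adjusted p = 0.867): Gdf9 rose by 0.75 ± 0.23 and Bmp15, its partner, by 0.82 ± 0.28 (SE), while Zp3 fell by 1.92 and Figla, a transcription factor of early oocytes, fell by 6.40. Maternal effect factors split likewise, 8 higher and 10 lower (median 0.13, mean −0.34, over 26 members, adjusted p = 0.705), with Nlrp5 up by 1.16 ± 0.44 (adjusted p = 0.0252, and over 0.05 without GV fresh replicate 1, 2 or 3), the histone chaperone Npm2 down to −3.36 ± 0.26 and the DNA methyltransferase Dnmt1 down to −1.18 ± 0.38. Without GV fresh replicate 4, Bmp15 (0.68) and Dnmt1 (−0.88) lost their calls, as they did with MII library numbers under 20 only (0.59 and −0.69). Dppa3 had 4083 ± 2853 CPM (SD, n = 4) in GV and 4701 ± 1697 CPM (SD, n = 12) in MII oocytes (adjusted p = 0.730).

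The largest rises were in genes near 0 in GV oocytes, and most of these are uncertain as counts. Mia2 had 0.0230 CPM in GV and 516 ± 58.5 CPM in MII oocytes and the histone variant H3f3b 0.515 and 2350 ± 560 CPM (SD, n = 12). Their values were not whole in 22 and 20 of 24 MII oocytes, and a difference in counting between the stages was not excluded for them. Tuba1c and Ncoa4 rose by 5.54 ± 0.61 and 4.99 ± 0.25 (SE) and share 61.0% and 43.1% of their 50-base words with other genes, and Ccnb1 shares 42.1%. Among genes with means near 0 in 1 stage alone, under 1 CPM in both groups of it and at least 16 in both groups of the other, 15 were near 0 in GV and 102 in MII oocytes.

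Stage cannot be separated from the library series or from how the values were made, since all GV libraries carry numbers of their own and hold whole values only. Of 6322 genes with whole values throughout, chosen after the data were seen, 1174 rose and 1486 fell, and there the histones had an adjusted p of 0.117. Such genes had lower stage changes than mostly fractional genes of like expression (at a mean log2 CPM of 4 to 6, medians of −0.49 and 1.06). Whether this choice itself favours falls, or the step that made the other values fractional raised them, was not tested. RLE scaling moved the median of all genes by −0.15 in fresh and −0.11 in vitrified oocytes, and changes are relative to that centre. The list test gave ribosomal proteins an unadjusted p under 0.05 in 59 of 99 other splits of fresh oocytes and 73 of 99 of vitrified ones. For oxidative phosphorylation these numbers were 65 and 70, and for histones 50 and 45. In fresh oocytes another split reached a ribosomal protein median of 5.11, against −4.57 in the real one. Each other split places GV oocytes among those called MII, so the stage difference itself enters these numbers and medians. They therefore give no measure of chance for the stage changes.

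Did oocytes from vitrified follicles pass through the same differences? In vitrified oocytes 2670 genes were higher and 3856 lower in MII than in GV oocytes, and stage took 54.8% of the variance (exact permutation p = 5.49e-04). Ccnb1 rose by 2.95 ± 0.36 (SE), to 9437 ± 2730 CPM (SD, n = 12), Btg4 by 2.44 ± 0.31 and Gdf9 by 1.47 ± 0.25, while Zp3 fell by 2.07, Sod1 fell by 6.16 and the proteasome subunit Psmb1 (chromosome 17, 15475021 to 15499751) fell by 7.11. Meiotic genes had a median of 1.24, 20 higher and 10 lower of 35 (adjusted p = 0.00656), and spindle genes 0.70, 14 higher and 6 lower of 29 (adjusted p = 0.0374). Ribosomal proteins had a median of −5.06 with 83 of 85 lower (adjusted p = 4.43e-20), oxidative phosphorylation −4.29 with 53 lower and 6 higher of 62 (4.86e-14) and proteasome subunits −2.19 with 25 lower and 5 higher of 36 (2.53e-04). With an estimated correlation the adjusted p of these 5 lists was 0.516. With fry it was 2.89e-08, 6.84e-05, 1.8e-09, 1.8e-09 and 2.2e-08, in the order given. Matched random genes had medians of −2.94 for ribosomal proteins and −2.53 for oxidative phosphorylation. Histones had 12 lower and 1 higher member of 23 and a median of −2.43 (adjusted p = 0.105). The spindle list had an adjusted p of 0.0584 with RLE scaling and 0.0579 with MII library numbers of 20 and over only, and the meiotic list had a median of −0.49 (adjusted p = 0.358) in its 10 members with whole values.

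Genes that differed between the stages were largely shared by the treatments. Of the 11470 genes, 2267 were higher in MII oocytes of both treatments and 3128 lower in both, against 608 and 1145 for independent sets, and 2 went in opposite directions. Only fresh oocytes gave a call for 618 genes and only vitrified ones for 1129. Across genes, which are not independent replicates, the log2 fold changes of the treatments had a Pearson correlation of 0.903 and a Spearman correlation of 0.911, with no oocyte in common. In both treatments, library series and the form of the values changed along with stage. A difference from either would be shared in the same way, so this likeness cannot tell them from stage.

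Did the difference between stages depend on vitrification? edgeR called 0 of 11470 genes for the interaction of stage and treatment, with 466 at an unadjusted p under 0.05. RLE scaling called 3, the stricter filter 2, DESeq2 8 and limma-voom 1 (486, 330, 523 and 829 unadjusted). Cpox, an enzyme of haem synthesis on chromosome 16 (58670292 to 58717636), had the smallest p: it measured 29.0 ± 1.11 CPM in fresh and 10.5 ± 4.66 CPM in vitrified GV oocytes (SD, n = 4 each) and 60.6 ± 14.7 and 80.4 ± 20.04 CPM in MII oocytes (SD, n = 12 each), an interaction of 1.88 ± 0.38 (SE, adjusted p = 0.0659). Next came the retinol dehydrogenase Rdh12 (1.73 ± 0.39) and Pole3 (1.25 ± 0.28), both at an adjusted p of 0.222, and on the other side Ranbp2 (−1.78 ± 0.45, adjusted p = 0.530). No list passed: oxidative phosphorylation had 54 of 62 members below 0 and a median of −0.63 (adjusted p = 0.183), and ribosomal proteins 75 of 85 and −0.61 (adjusted p = 0.383). For Gdf9 the interaction was 0.72 ± 0.32 and for Nlrp5 −0.91 ± 0.58 (SE), both at an adjusted p of 1, so the Nlrp5 rise of fresh oocytes was not shown to differ from the value of 0.26 ± 0.41 in vitrified ones.

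The genes of the few interaction calls made by other settings are named here, a choice made after their values were seen. Besides Cpox, RLE scaling called Clec2h, a C-type lectin gene (5.97, adjusted p = 0.0492), and Khdrbs2, an RNA-binding protein gene (7.88, adjusted p = 0.0492). The stricter filter called Cpox (1.91) and Clec2h (5.89), both at an adjusted p of 0.0431, and limma-voom called Lypd3 alone (7.39, adjusted p = 0.0179). The 8 genes of DESeq2 were Cpox (1.95, adjusted p = 2.75e-04), Clec2h (6.33), Khdrbs2 (8.08), Evi2b (4.18), Plk3 (3.78), Rdh12 (1.78, adjusted p = 0.0254) and Pole3 (1.31, adjusted p = 0.0333), all higher, and Fads2b, lower, which was at 0 in all GV fresh oocytes, so that its fold has no finite estimate. Without GV fresh replicate 2, edgeR called Clec2h, Khdrbs2, Evi2b (4.45) and Pole3 (1.43). Without GV fresh replicate 4 it called Clec2h (6.27), and without GV vitrified replicate 4 Efhd1 (7.15).

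Did the libraries themselves differ between treatments? Ribosomal protein transcripts summed to 22787 ± 1397 CPM in fresh and 17845 ± 2999 CPM in vitrified GV oocytes (SD, n = 4 each, exact p = 0.0286, the smallest that 4 against 4 can give, and 0.504 adjusted over 24 quality tests). Oxidative phosphorylation transcripts summed to 15552 ± 3062 and 12286 ± 1484 CPM (exact p = 0.0857). Summed markers of granulosa and cumulus cells were 272 ± 78.7 and 260 ± 59.3 CPM in GV oocytes (SD, n = 4 each, exact p = 0.886), and 2926 ± 1928 and 2850 ± 762 CPM in MII oocytes (SD, n = 12 each, permutation p = 0.943). Most of the MII sum came from Serpine2, a protease inhibitor, at 2401 ± 783 CPM in fresh MII oocytes. Whether the oocyte or attached cells made this transcript was not tested.

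**Figure D4:**
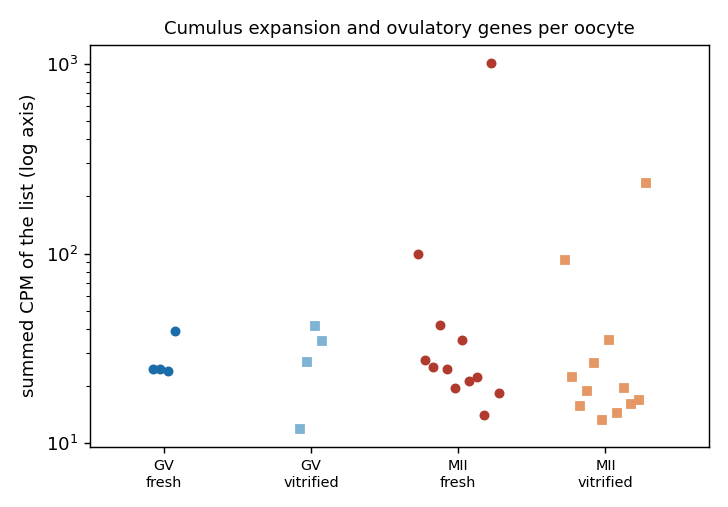
Summed CPM, on a log axis, of cumulus expansion and ovulatory genes in each oocyte, by group. MII fresh replicates 11 and 1 (1010 and 99.0 CPM) and vitrified replicates 12 and 1 (235 and 92.0 CPM) stand above the others, which hold at most 41.9 CPM.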

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

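The values in the next paragraph were found by a rule for single oocytes far from the other 3 of their group, and of the tests that follow, those on fractional counting, those on cumulus cells, the omissions in the test of length and GC content and the splits of list medians were chosen only after the result was seen.

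The rule, Dixon's ratio above its 95% critical value for 4 oocytes, was applied to 52 groups of values, where chance flags about 1 in 20 groups, or 2.6 here. GV vitrified replicate 1 had 9.39% of its counts in the 10 highest genes, against 4.93% to 5.62% in the others. Its Dppa3 value was 16590 CPM, against 1339 to 3503. Its oxidative phosphorylation transcripts summed to 14490 CPM, against 11270 to 11720. GV fresh replicate 3 had 20100 CPM of the same transcripts, against 13700 to 14670. GV fresh replicate 4 had 2914 CPM of Zp3, against 1207 to 1252. Its cumulus expansion transcripts summed to 38.9 CPM, against 24.01 to 24.7. GV fresh replicate 1 had 40.8 CPM of Inha, against 1.10 to 6.66. Its transcripts of theca, stroma, blood, endothelial and immune cells summed to 12.1 CPM, against 25.04 to 25.9. GV vitrified replicate 2 had 349 CPM of granulosa cell transcripts, against 228 to 232.

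The first pattern weighed is the lower level of ribosomal protein and oxidative phosphorylation transcripts in vitrified MII oocytes. Without the 4 oocytes with a cumulus signal the ribosomal score still differed by −0.34 (permutation p = 0.263), which cannot tell whether cumulus RNA was the cause. For transcript length and GC content, oxidative phosphorylation genes had a median of −0.94, below the 2.5th percentile of −0.39 of matched random lists. Without fresh replicate 11 these values were −0.41 and −0.26. The random lists take genes as independent, while the list members correlated at 0.53. That limit is thus too narrow to exclude length and GC content as the whole cause. The treatment change resembled the change from GV to MII across genes (Spearman rho 0.321, exact permutation p = 0.0238, in library numbers of 20 and over, and 0.266, p = 0.0437, in those under 20), so vitrified MII oocytes may stand further along the loss of these transcripts. Without the 4 oocytes rho was 0.240 (exact permutation p = 0.0857) and 0.179 (p = 0.141). Medians as far from 0 arose in 5 of 100 splits for ribosomal proteins (highest other 1.27, real −0.97) and 2 of 100 for oxidative phosphorylation (1.07, real −0.93), and in GV oocytes in 1 of 35 (0.37, real −0.41), 3 of 35 (0.43, real −0.34) and, for histones, 5 of 35 (0.83, real −0.65).

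The second pattern is the fall of the same transcripts from GV to MII. For fractional counting, oxidative phosphorylation genes with whole MII values (41 of 62) had a median of −4.14 in fresh oocytes. This was below the 2.5th percentile of −3.15 (median −2.10) of other whole-valued genes of like GV expression. But whole values go with few MII reads, so the fall itself helps to choose these genes. Nor does a whole value show that a gene was counted as in GV oocytes, so this test cannot decide. Reads shared with pseudogene copies were tested through exact words shared with other genes. In oxidative phosphorylation, members with at most 5% shared words had a median of −3.39, so copies sharing such words were not the whole cause there. For ribosomal proteins this cannot tell, since only 3 such members exist (median −3.73). Copies with differences inside each word are not counted in this way but could still share reads. Pseudogene copies were thus not excluded for either list. A difference between library series cannot be told from stage, since 0 MII libraries carry numbers of the GV series. A loss or shortening of poly(A) tails during maturation could give the same values and was not tested apart from the loss of the transcripts.

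The third pattern is the cumulus signal in 4 MII oocytes. Of 21 granulosa and cumulus markers, 13 in fresh replicate 11 exceeded all 20 oocytes without the signal, more than the 11 of the highest of those 20 against the rest, which fits RNA of cumulus cells. The counts of 10 in vitrified replicate 12, 7 in fresh replicate 1 and 3 in vitrified replicate 1 cannot tell. The median of those 20 oocytes was 0. Vitrified replicate 7, which is among them, had 41.2 CPM of Inha, against 39.5 in fresh replicate 1 and 48.3 in vitrified replicate 1. Those 20, and so the fits without the 4 oocytes, may not be free of such RNA. Reads carried over from fresh replicate 11 into vitrified replicate 12 were excluded as the whole cause, since Cyp11a1 had 62.0 CPM in the latter and 10.8 CPM in the former. Ereg (10.1 against 1.83) and Areg (1.79 against 0) were higher in the latter too. Other such genes were lower there, among them Hsd3b1 (252 against 2249) and Inha (193 against 1667). A part carried over was thus not excluded. No biological explanation was tested for this signal.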

How the results depend on the processing

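The settings without 4 oocytes and with whole values only were added after the data were seen. Of gene values that named genes took under the alternatives, 1553, 3384, 2946, 2942 and 4122 stayed on the same side of the threshold in the GV, MII, fresh stage, vitrified stage and interaction comparisons (44, 48, 4, 8 and 50 of them, none past the threshold, with the other sign), and 59 and 51 were weaker in the stage comparisons. Single omissions gave 0 calls in GV, 0 to 1 in MII, 5399 to 6247 and 6017 to 6575 in the fresh and vitrified stage comparisons and 0 to 4 in the interaction. They gave interval shares of 10.0% to 21.9% (GV) and 60.8% to 63.8% (MII), variance shares of 12.5% to 16.03% and 5.47% to 7.14%, and distance differences of −0.0157 to 0.0376 and −0.0121 to −2.41e-04.

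The following differed, and the cause was not tested. MII calls were 52 with DESeq2 and 1 with the stricter filter or the fit of all oocytes. Interaction calls were 3 (RLE), 2 (stricter filter), 8 (DESeq2) and 1 (limma-voom). The GV interval share was 32.8% with limma-voom. Stage calls were 2660 and 3023 with whole values only, where fewer genes were tested. Inha turned to −5.45 in fresh and −3.90 in vitrified oocytes with limma-voom and to −6.04 in fresh ones without the 4 oocytes. Dppa3 ran from −0.65 to 0.94 in vitrified oocytes when single GV vitrified oocytes were left out, the latter without replicate 1. MII distance differences were 0.00299 and −0.0308 within the library series and 8.75e-04 without the 4 oocytes.

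With replicate number as a block, calls were 0 (GV), 0 (MII), 4683, 4908 and 0, interval shares were 13.7% and 58.7%, Inha turned to −4.34 in fresh oocytes, and the interaction lists of nuclear oxidative phosphorylation subunits (median −0.55), proteasome subunits (−0.35, adjusted p = 0.0486) and replication-dependent histones (1.06, adjusted p = 0.0486) passed. The stage and interaction fits with this block held only replicate numbers up to 4, and their MII oocytes all had library numbers under 20. The stage fits tested 10210 (fresh) and 9972 (vitrified) genes. In these fits the block cannot be told apart from the choice of oocytes. Equal numbers correlated at −0.381 to 0.182 in GV and −0.336 to 0.327 in MII oocytes, with medians of 0.054 and 0.0716 against −0.0318 and −0.0144 for unequal numbers. Of these pairs, 2 of 4 and 6 of 12 were over 0.1, and 1 GV and 0 MII fresh oocytes correlated best with their own number, so not every pair deviated together. With 4 oocytes per group, 1% of simulated 2-fold changes were recovered in GV oocytes.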

Other observations

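In this part, the splits of unadjusted counts were chosen only after the result was seen.

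Several lists of other functions held genes that changed between the stages in fresh oocytes without passing as lists. In the endoplasmic reticulum stress list (median 0.45 over 27 members, adjusted p = 0.328), the stress sensor Ern1 rose by 3.04 and the pro-death factor Ddit3 fell by 5.99. In lipid and sterol metabolism (median 0.32 over 32, adjusted p = 0.394), Idi1 rose by 4.54 while Fdft1, a later enzyme of the same sterol pathway, fell by 4.31. Among apoptosis and DNA damage genes (median 0.01 over 30, adjusted p = 0.314), Trp53 rose by 2.55 and its antagonist Mdm2 by 2.18. Antioxidant enzymes split into 9 higher and 13 lower (median −0.17 over 34, adjusted p = 0.594), with Selenow down to −3.49 and Glrx5 up by 8.15. Chromatin modifiers had 11 higher and 8 lower (median 0.26 over 39, adjusted p = 0.349), among them the histone acetyltransferase Kat8, which fell by 4.35, and the demethylase Kdm6a, which rose by 1.92. Of fertilization genes (median −0.11 over 25, adjusted p = 0.988), the sperm receptor Izumo1r fell by 3.31 and the zinc transporter Slc39a10 rose by 1.94.

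Markers of somatic cells and of handling did not pass as lists in fresh oocytes either. Immediate early genes had a median of 2.00 over 16 members (adjusted p = 0.463), granulosa and cumulus markers 1.04 over 16 (0.652), cumulus expansion genes 4.199 over 6 (0.821) and markers of other cells 0.90 over 8 (0.425). Heat and cold shock genes had a median of 0.18 and a mean of −0.09 over 24 members (adjusted p = 0.761), with the chaperone Dnajb1 down to −2.26.

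A hypothesis was tested that transcripts with a cytoplasmic polyadenylation element near the annotated 3' end are kept or gain tails during maturation. Genes with the element had a median MII minus GV change of 0.49 in fresh and 0.51 in vitrified oocytes, and genes without it −0.35 and −0.50. The upper 95% limits of random genes matched to them were 0.15 and 0.09, so the values fit the hypothesis. These limits take genes as independent. In vitrified against fresh MII oocytes, genes with the element also lay above their limit (0.06 against 0.02), so passing was not particular to maturation. In fresh oocytes 35.1% of genes with the element rose, against 20.5% without it. Among genes with whole MII values the median was −0.04, against −0.62 in matched genes. These values are consistent with tail lengthening, but transcript amount and tail length were not measured apart.

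Other splits of the same oocytes were fitted as well. Where the real split gave 0 calls, every split has as many (35 of 35 in GV oocytes, 100 of 100 in MII oocytes and 100 of 100 for the interaction), which decides nothing. The highest other splits gave 271, 69 and 415 calls, which points to a structure among the oocytes besides treatment. In GV oocytes 22 of 35 had at least 180 genes at an unadjusted p under 0.05 (highest other 2555). In MII oocytes 5 of 100 had at least 1052 unadjusted (highest other 1874). The stage comparisons gave 6015 and 6526 calls, reached by 1 of 100 splits each, the real one (highest other 3958 and 2949). For the interaction, 71 of 100 had at least 466 unadjusted (highest other 2222).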
